A study of Drosophila melanogaster with 18 samples.

How the data were processed

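RNA was measured in 18 libraries of DL1 cells, a haemocyte-like line of Drosophila melanogaster, in 6 groups of 3. Per the labels' protocols, cells were bathed in 2 µg of double-stranded RNA (dsRNA), which fly cells take up and use for RNA interference, and were grown for 3 days. The dsRNAs were directed against IntS4, IntS6, mts or Pp2A-29B, against the bacterial B-gal gene as a control, or left out in the Mock group. IntS4 and IntS6 encode subunits of Integrator, a complex that cleaves nascent RNA, and mts and Pp2A-29B encode the catalytic and scaffold subunits of protein phosphatase 2A (PP2A). Each group has 1 library in each of 3 biological replicate sets (A, B and C). Total RNA was depleted of ribosomal RNA and made into strand-specific libraries, per the labels' protocols.

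The authors deposited 1 table of estimated counts per gene and library, not normalized. Its values need not be whole: 90.1% lay within 0.005 of a whole number, and the rest were fractions, as when a read is divided among several genes or places. The submitters' processing notes name the read trimmer Trimmomatic 0.39, the read counter featureCounts, and the genome builds dm6 and BDGP6, without giving their settings. The aligner is not given in the sources used here. The division of reads makes values of near-identical gene copies (histones, Hsp70 copies, snRNA copies) and of overlapping genes uncertain. The test was planned for whole counts, so the estimated counts were rounded to whole numbers before use.

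The table holds 17753 gene entries, of which 17626 are in the Ensembl 115 annotation of BDGP6, which gave 17625 symbols and all coordinates. The 128 entries without a symbol took 0.48% of counts and were kept under their identifiers. No count was seen for 3092 entries. Library totals ran from 13445318 to 19298644 counts. The 138 ribosomal RNA entries took 65.1 to 74.8% of them, which left 3545828 to 6325688 counts per library for all other genes. The pre-rRNA gene CR45847 took 18.9% of all counts. No 2 libraries held identical values, and replicate libraries correlated at 0.977 to 0.994.

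Differences were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test on 1 fit of all 6 groups, with TMM factors. Genes were kept by filterByExpr with a count minimum of 10, which left 8704 genes with 12 residual degrees of freedom and a common biological coefficient of variation of 0.131. Genes with an adjusted p under 0.05 (Benjamini-Hochberg over all genes tested in a comparison) are called changed. Every adjusted p of a gene comes from this test unless an alternative or a left-out library is named beside it. Standard errors are the log2 fold change divided by the square root of F. CPM are counts scaled to the total of the library, ribosomal RNA included, after that total was multiplied by the TMM factor of the library. They therefore differ from counts divided by the plain library total, as do the percentages of the B-gal level taken from them. All tests are two-sided unless stated otherwise. A fold against 3 libraries without a count is a lower bound, set against 3 counts over the group. For 1 to 3 counts the ratio of normalised counts is given with its exact 95% counting interval. Bounds and intervals cover counting error only, since reads copied by PCR are not independent molecules. Fitted fold changes of genes with a few counts in B-gal depend on the prior count.

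The comparisons were B-gal against Mock, each of the 4 other dsRNA groups against B-gal, and 4 direct comparisons between these groups. Of 43 gene lists fixed in advance, 39 had at least 5 tested members and were tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01, with adjustment over 39 lists and 9 comparisons. Each test was repeated with the correlation estimated from the libraries. The lists, tests, groups and the rule for named genes were chosen before the data were examined. That rule takes the 4 targeted genes in each of the 4 groups. It takes the 6 highest and 6 lowest log2 fold changes of each of them, among changed genes with a mean log2 CPM of at least 2 and no overlap between the libraries of the 2 groups. In direct comparisons it takes 4 per direction. It also takes up to 4 members with the smallest adjusted p in each list past its test, every tested gene of 1 list of reported Integrator targets, and the 6 genes per direction with the largest change shared by all 4 groups, under the same limit on mean log2 CPM.

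Replicate letters were checked for pairing as the correlation of same-letter deviations from group means. All 3 pairs were above 0.1 for B-gal and Mock (lowest 0.57), IntS4 and B-gal (0.38) and IntS6 and B-gal (0.25). The same held for mts and B-gal (0.13) and for Pp2A-29B and mts (0.17). These are called paired comparisons below. For mts and B-gal, libraries of different letters correlated at up to 0.23. The other 4 had a lowest value of 0.06 or less, although every group has 1 library in each replicate set. The fits without the replicate set as a block are the ones reported, as planned. Comparisons that share the B-gal libraries share their chance values, so 24 simulations of unchanged groups against a simulated B-gal group were drawn. Overlaps were also recomputed with B-gal as the control of 1 group and Mock of the other.

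The steps were tested on simulated data. For IntS4 against B-gal, over 7978 genes, 45 of 67 genes changed 2-fold were recovered (67.2%), 58 of 66 changed 4-fold (87.9%) and 26 of 67 changed 1.5-fold (38.8%), and 10 of 139 calls were of unchanged genes. Alternatives were DESeq2 1.42.0, RLE factors, no filter, the replicate block, only the 2 groups compared, Mock as the control, a minimum of 1.5-fold and leaving out each library in turn. After seeing the data, fits without ribosomal RNA entries, with a term for ribosomal RNA composition, and other reaches around snRNA genes were added. No deposited column was left out.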

Results

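The series asks how gene expression in DL1 cells changes when a subunit of the Integrator complex (IntS4 or IntS6) or of the PP2A core enzyme (mts or Pp2A-29B) is depleted by RNA interference. PP2A binds Integrator, which places its subunits beside those of Integrator in the design. There are 6 groups of 3 libraries: Mock, B-gal dsRNA (the control), and dsRNA against each of the 4 genes. Library totals ran from 13445318 (IntS6 replicate C) to 19298644 counts (IntS4 replicate B), and 3545828 (mts replicate C) to 6325688 of them (IntS4 replicate B) fell outside ribosomal RNA. The share of ribosomal RNA was highest in the mts libraries, at 73.0 to 74.8%, against 66.3 to 71.8% with B-gal dsRNA. Over 5904 genes with a mean log2 CPM of at least 2, the first principal component held 54.9% of the variance and the second 27.9%. On the first, libraries labelled IntS4 and IntS6 dsRNA lay between 30.4 and 39.2, and Mock and B-gal libraries between -37.6 and -33.1. On the second, the mts libraries lay between -35.8 and -33.5 and the Pp2A-29B libraries between -22.3 and -20.3, below all other libraries.

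The targeted genes were lower in 2 of the 4 dsRNA groups and higher in the other 2. The transcript of mts (chromosome 2L, 7827650 to 7833576, plus strand) fell to 42.6% of its B-gal level with its own dsRNA, 64 ± 15.4 against 150 ± 16.3 CPM (SD, n = 3), a log2 fold change of -1.23 (SE 0.14, adjusted p = 1.1e-06). Pp2A-29B (2L, 8366038 to 8370090, plus strand) fell to 29.2%, 45.9 ± 3.69 against 157 ± 8.13 CPM, a log2 fold change of -1.78 (SE 0.08, adjusted p = 3.7e-11). IntS4 (X, 8555239 to 8558781, minus strand) was instead higher in the libraries labelled IntS4 dsRNA, at 98.8 ± 111 against 12.1 ± 0.191 CPM. Its log2 fold change was 3.02 (SE 0.51, adjusted p = 7.6e-05). The 3 libraries held 3111, 853 and 401 IntS4 counts in sets A, B and C, against 179 to 216 in the B-gal libraries, and the log2 value was 1.52 without the set A library. IntS6 (X, 5738663 to 5747254, minus strand) was likewise higher in the libraries labelled IntS6 dsRNA, at 83.9 ± 57.6 against 29.8 ± 3.26 CPM. Its log2 fold change was 1.5 (SE 0.29, adjusted p = 0.00031), and 0.76 without the set A library, which held 2682 IntS6 counts against 795 and 722. Counts over the whole gene therefore do not show a loss of either Integrator transcript, and these groups are named by their labels below. IntS6 was 0.68 in the libraries labelled IntS4 dsRNA (adjusted p = 0.06, 0.019 with the replicate block, and 0.0015 to 0.16 over its alternatives). It was also 0.49 with mts and 0.52 with Pp2A-29B dsRNA (adjusted p = 0.17 each), and passed there without the filter (0.55 each, adjusted p = 0.019 and 0.023) and with only the 2 groups compared (0.51 and 0.53, adjusted p = 0.007 and 0.0053). In both Integrator-labelled groups, mts was lower by a log2 fold change of -0.51 (adjusted p = 0.0052 with IntS4 and 0.0056 with IntS6 dsRNA). Pp2A-29B fell too, by -0.37 and -0.33 (adjusted p = 0.00071 and 0.0021).

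**Figure D1:**
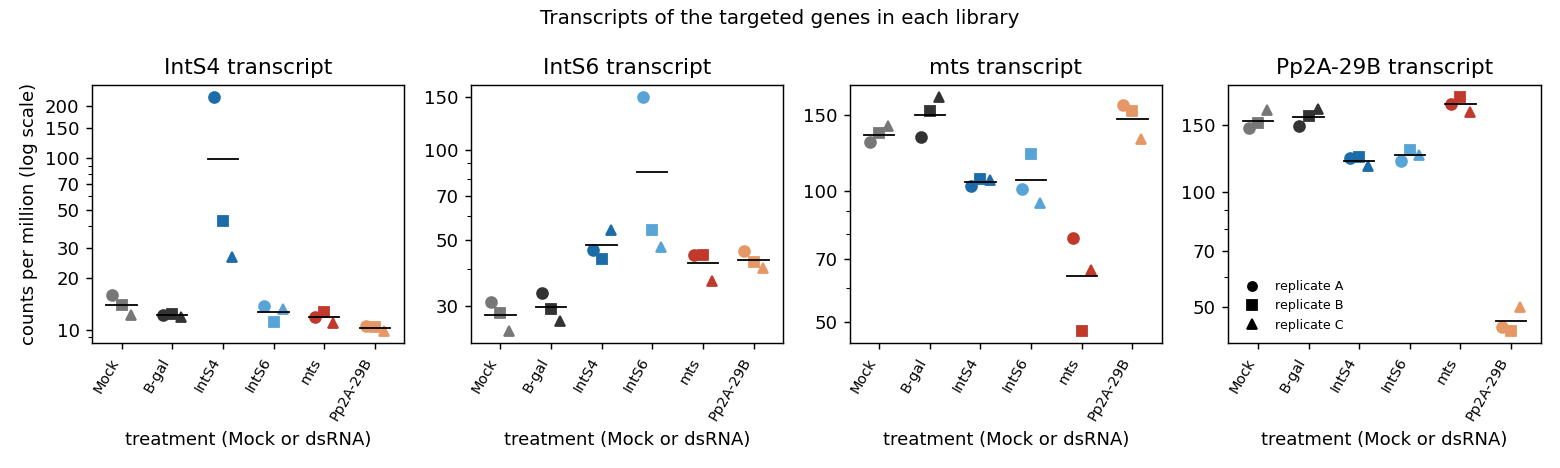
CPM (log axis) of the 4 targeted genes in each of the 18 libraries, by group, with markers for replicate sets A, B and C and a line at each group mean. IntS4 and IntS6 lie highest in their own dsRNA libraries, at means of 98.8 and 83.9 CPM, while mts and Pp2A-29B lie lowest in theirs, at 64 and 45.9 CPM.

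Control dsRNA against Mock treatment shows what dsRNA uptake itself does to these cells. The targeted genes, the stress and antimicrobial genes and all others stayed under the threshold: edgeR called 0 of 8704 genes, with 245 at an unadjusted p under 0.05, and DESeq2 called 0, with 198. With the replicate block, edgeR called 0 too, with 360 at an unadjusted p under 0.05. Cytosolic ribosomal protein genes had a median log2 fold change of -0.10 and proteasome genes of -0.08, with 0 members called in either list, also when adjusted over the list alone. At the preset correlation of 0.01 both passed camera (adjusted p = 6.5e-06 and 2.5e-05), as did 11 of 39 lists in all. Among these were oxidative phosphorylation (median -0.08), glycolysis (-0.12) and extracellular matrix genes (-0.14). Neither of the first lists passed with an estimated correlation (adjusted p = 0.71 and 0.27 with an estimated correlation), nor did any other of the 39. In this control comparison the preset test thus passed lists without a called member.

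In the libraries labelled IntS4 dsRNA, in which IntS4 counts were themselves higher, 2338 genes were higher and 1756 lower than with B-gal dsRNA (47% of 8704). Among genes with a mean log2 CPM of at least 2, the limit of the naming rule, several that rose were almost silent in control cells. Tig, which encodes the matrix protein Tiggrin, stood at 548 ± 8.66 against 1.53 ± 0.212 CPM (SD, n = 3), a log2 fold change of 8.47 (SE 0.23, adjusted p = 2e-15). Hml, which encodes the haemocyte clotting factor Hemolectin, stood at 609 ± 173 against 2.86 ± 0.811 CPM, a log2 fold change of 7.72 (SE 0.34). Ect3 reached 201 ± 3.26 from 0.291 ± 0.183 CPM, SKIP 142 ± 6.4 from 0.388 ± 0.139, and the alpha-tubulin gene alphaTub85E 86.6 ± 6.68 from 0.124 ± 0.0748. Ance, a peptidase related to angiotensin-converting enzyme, stood at 50.2 ± 0.805 CPM against 5 counts in B-gal, all in set B, so its log2 value of 8.87 became 12.63 without that library and 8.27 without the set C control. Decreases were smaller. The lowest gene within the same limit was LUBEL, a linear ubiquitin ligase, at 3.25 ± 0.382 against 22.2 ± 2.96 CPM (log2 -2.78, SE 0.23, adjusted p = 1.1e-08), followed by the carbonyl reductase gene sni (-2.48), nAChRalpha5 (-2.35), the Wnt deacylase gene Notum (-2.34), CG6118 (-2.09) and CG15093 (-1.86). Among changed genes, 886 were at least 4-fold higher and 30 at least 4-fold lower, and at 16-fold the numbers were 428 and 2. Of the higher genes, 31.8% were under 1 CPM in Mock, against 15.8% of all tested and 1.8% of the lower genes. A gene with few counts in the control libraries passes the filter mainly where a dsRNA group raises it, and can hardly be called lower. Such shares, here and for the other groups below, are thus set in part by the filter.

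The list of 10 tested genes reported elsewhere as repressed by Integrator was higher as a group in the libraries labelled IntS4 dsRNA. Its 8 higher members, 8 also when adjusted over the list alone, included pst (720 ± 35.9 against 50.8 ± 2.25 CPM, log2 3.83), ana (5.48), Sirup (4.43) and CG6847 (5.14). Pepck1, for the gluconeogenic enzyme, had a log2 fold change of 9.47, which was 10.10 without the set A control and 8.85 without the set C control. CG8620 had 3 B-gal counts and a ratio of 158 (95% counting interval 53.7 to 769), and its fitted value of 7.13 was 7.92 without the set C control. Mkp3 and MtnA did not pass (0.13, SE 0.10, and -0.17, SE 1.34), and MtnA varied between 15.3 ± 21.5 CPM within B-gal. The median was 4.79, and it did not move with CG8620 at its lower limit. The test held both ways (camera adjusted p = 1.9e-15, and adjusted p = 0.00084 with an estimated correlation). Naam was 0.74 (adjusted p = 0.012) and missed the threshold without the set C control (0.49, adjusted p = 0.07). Oxidative stress genes rose, 10 higher and 1 lower of 12 (10 and 2 adjusted over the list alone), with catalase Cat at 2.33 and the glutathione transferase GstD1 at 2.28 (SE 0.12). Their test held too (adjusted p = 8.1e-05, and adjusted p = 0.037 with an estimated correlation).

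Other groups in the IntS4-labelled libraries passed at the preset correlation alone. Genes of oxidative phosphorylation were lower in 50 and higher in 2 of 68 (51 and 2 adjusted over the list alone), with a median of -0.61. ATPsynC was at 170 ± 14.6 against 349 ± 40.9 CPM (-1.04, SE 0.11) and Cyt-c1 at -1.17 (camera adjusted p = 3e-08, and adjusted p = 0.42 with an estimated correlation). Heat shock proteins were higher in 13 and lower in 1 of 15, the same numbers adjusted over the list alone, with the small heat shock genes Hsp23 at 3.59 and Hsp27 at 2.24 and the co-chaperone DnaJ-1 at 1.63 (adjusted p = 2.5e-05, and adjusted p = 0.27 with an estimated correlation). The Hsp70 copies in that list share reads and are uncertain singly. Extracellular matrix genes were higher in 11 and lower in 1 of 15 (11 and 2 adjusted over the list alone), among them the perlecan gene trol (643 ± 51.9 against 124 ± 8.14 CPM), Mmp2 (5.68) and the collagen gene Col4a1 (4.65) (adjusted p = 7.4e-05, and adjusted p = 0.23 with an estimated correlation). Markers of plasmatocytes, the macrophage-like haemocytes, were higher in 10 and lower in 0 of 12, adjusted over the list alone too, with NimC1 at 4.38 (5.39 without the set C control) and vkg at 3.36 (adjusted p = 0.00054, and adjusted p = 0.27 with an estimated correlation). Lists share members: vkg is in the extracellular matrix list too, and Hml is both a plasmatocyte marker and a reported Integrator target. Tests of these lists are thus not independent, here and in the other groups. Markers of lamellocytes, the encapsulating haemocytes, were higher in 6 and lower in 0 of 9, adjusted over the list alone too, with PPO3 at 5.19 (adjusted p = 0.03, and adjusted p = 0.58 with an estimated correlation). Antimicrobial and immune pathway genes were higher in 7 of 8, adjusted over the list alone too, with the cecropin CecA1 at 6.86 and Rel at 1.06 (adjusted p = 2.7e-05, and adjusted p = 0.068 with an estimated correlation). Only 8 of the 25 genes found for that list passed the filter. It keeps genes with few control counts mainly where a dsRNA group raises them, so this share is set in part by the filter. Amino acid and ATF4 response genes were higher in 10 and lower in 1 of 14, adjusted over the list alone too, with asparagine synthetase AsnS at 2.95 (adjusted p = 0.0029, and adjusted p = 0.097 with an estimated correlation). Glycolysis genes were higher in 11 and lower in 0 of 14, adjusted over the list alone too, with Pfk at 1.39 (adjusted p = 0.0015, and adjusted p = 0.39 with an estimated correlation). Mitosis genes were lower in 20 and higher in 3 of 29 and DNA replication genes lower in 13 and higher in 3 of 20, both also adjusted over the list alone, with CycB at -0.65 and CycE at -1.23 (adjusted p = 0.0015 and 0.018, and adjusted p = 0.23 and 0.62 with an estimated correlation). Integrator's own 14 tested subunit genes did not move together, with 4 higher and 3 lower, adjusted over the list alone too (camera adjusted p = 0.99).

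In the libraries labelled IntS6 dsRNA, in which IntS6 counts were themselves higher, 2291 genes were higher and 1686 lower (45.7%). Ect3 (8.49, SE 0.68), Tig (8.24, SE 0.22), Hml (7.70, SE 0.34), SKIP (7.30, SE 0.23) and the glutamine synthetase gene Gs2 (6.64, SE 0.56) had the largest log2 fold changes by the naming rule, with Ance at 7.93 on its 5 B-gal counts (11.69 without the set B control and 7.33 without the set C control). Tig stood at 466 ± 115, Hml at 601 ± 153 and Gs2 at 73.7 ± 4.5 CPM (SD, n = 3). The lowest by that rule were LUBEL (-2.49, SE 0.23), nAChRalpha5 (-2.15), the mitochondrial seryl-tRNA synthetase gene SerRS-m (-2.11, SE 0.16), the spliceosomal gene SmD3 (-1.65), Notum (-1.63) and sni (-1.61). At least 4-fold changes were seen in 873 higher and 19 lower genes, and at least 16-fold ones in 404 and 1. Of the higher genes 31.6% were under 1 CPM in Mock, against 1.1% of the lower genes.

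The reported Integrator targets were again higher in the libraries labelled IntS6 dsRNA, in 8 of 10 and lower in 0 (8 and 1 adjusted over the list alone), with a median of 3.94, also with CG8620 at its limit (camera adjusted p = 7.1e-14, and adjusted p = 0.0013 with an estimated correlation). pst stood at 661 ± 17.4 CPM (log2 3.70), ana at 4.08, Sirup at 3.79 and CG6847 at 4.86, Pepck1 at 7.68 (8.32 without the set A control and 7.06 without the set C control) and CG8620 at a ratio of 128 (43.5 to 625), with a fitted value of 6.82 that was 7.62 without the set C control. Naam (0.59, adjusted p = 0.044) missed the threshold without B-gal set A (0.64, adjusted p = 0.062) or C (0.34, 0.22) and without IntS6 set A (0.60, 0.077) or B (0.44, 0.18). Mkp3 was -0.22 (adjusted p = 0.08, 0.048 with the replicate block, and 0.014 to 0.23 over its alternatives), and MtnA was 0.20 (SE 1.33). Antimicrobial and immune genes rose in 7 of 8, adjusted over the list alone too, with CecA1 at 6.19, PGRP-SA at 2.73 and pirk at 2.45 (adjusted p = 3.8e-06, and adjusted p = 0.037 with an estimated correlation). As above, these 8 are the ones of 25 that passed the filter, which can favour raised genes. Other groups passed at the preset correlation alone. Oxidative phosphorylation genes were lower in 44 and higher in 1 of 68 (48 and 2 adjusted over the list alone), with ATPsynC at -0.88 (adjusted p = 1.2e-07, and adjusted p = 0.45 with an estimated correlation). Heat shock proteins were higher in 13 and lower in 1 of 15, adjusted over the list alone too, with Hsp23 at 2.94 (adjusted p = 0.002, and adjusted p = 0.45 with an estimated correlation). Extracellular matrix genes were higher in 12 and lower in 1 of 15 (13 and 1 adjusted over the list alone), with trol at 2.34 and Mmp2 at 4.86 (adjusted p = 1.6e-06, and adjusted p = 0.15 with an estimated correlation). Plasmatocyte markers were higher in 11 and lower in 0 of 12, adjusted over the list alone too, with vkg at 4.06 (adjusted p = 0.00016, and adjusted p = 0.24 with an estimated correlation). Lamellocyte markers were higher in 6 and lower in 0 of 9 (7 and 0 adjusted over the list alone), with PPO3 at 3.43 (adjusted p = 0.046, 0.058 with the replicate block, and adjusted p = 0.62 with an estimated correlation). Oxidative stress genes were higher in 9 and lower in 1 of 12 (10 and 1 adjusted over the list alone), with Cat at 2.08 (adjusted p = 0.0013, and adjusted p = 0.077 with an estimated correlation). Mitosis genes were lower in 19 and higher in 2 of 29 (20 and 2 adjusted over the list alone), with fzy at -0.74 (adjusted p = 8e-04, and adjusted p = 0.2 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 44 of 86 (49 adjusted over the list alone), with RpS27A at 208 ± 26.6 against 334 ± 15.2 CPM (adjusted p = 8.7e-06, and adjusted p = 0.72 with an estimated correlation), a list that also passed at the preset correlation in the B-gal and Mock comparison.

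With mts dsRNA, 2311 genes were higher and 2165 lower (51.4% of those tested). Notum fell to 1.64 ± 0.879 from 38.1 ± 9.7 CPM (SD, n = 3), a log2 fold change of -4.55 (SE 0.48, adjusted p = 3.5e-07), and the tetraspanin gene TM4SF to 4.69 ± 0.527 from 71 ± 19.8 CPM (-3.92, SE 0.35). The serotonin receptor gene 5-HT1B was at -3.95 and CG6118 at -4.0. The overlapping genes beat-IIIa and CG34106 held identical values (-4.60 each) and cannot be read singly. The highest by the naming rule were Ance (7.13), alphaTub85E (6.83), Ect3 (6.82), the diacylglycerol kinase gene Dgk (6.16), mdu (6.13) and CG7778 (5.99, SE 0.28). CG7778 reached 52.5 ± 10.8 from 0.816 ± 0.0763 CPM. These genes were highest in the set C library, with Ect3 at 29.2, 13.2 and 55.7 CPM in sets A, B and C. Without that library the log2 values were 6.38 for Ance, 6.17 for alphaTub85E, 6.21 for Ect3, 5.51 for Dgk, -4.68 for CG6118 and -5.64 for beat-IIIa. Ance was 10.90 without the set B control and 6.53 without the set C control. At least 4-fold changes were seen in 475 higher and 201 lower genes, and at least 16-fold ones in 137 and 23. Of the higher genes 19.8% were under 1 CPM in Mock.

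Mitosis genes fell with mts dsRNA. Of 29, 25 were lower and 0 higher (26 and 1 adjusted over the list alone), with a median of -0.71, and among them were the spindle gene asp (27.2 ± 2.28 against 75.3 ± 7.09 CPM, -1.47, SE 0.11), the condensin gene Cap-D2 (-1.24), the kinase gene polo (-0.97) and cyclin CycB (-0.90). The test held both ways (camera adjusted p = 5.1e-10, and adjusted p = 0.019 with an estimated correlation). Oxidative stress genes rose, 10 of 12 with 0 lower, adjusted over the list alone too (adjusted p = 1e-06, and adjusted p = 0.018 with an estimated correlation). GstD1 reached 951 ± 48.7 from 82.5 ± 8.32 CPM (3.53, SE 0.12), Gclc was at 1.54, and GstD2, with no count in the B-gal libraries, was at least 62.8-fold higher. Lamellocyte markers were higher in 9 of 9, adjusted over the list alone too (adjusted p = 6.6e-08, and adjusted p = 0.18 with an estimated correlation). Among them the filamin gene cher stood at 782 ± 131 against 187 ± 17.2 CPM (2.07), PPO3 at 4.63, atilla at 6.47 and the integrin gene ItgaPS4 at 10.24 on 4 B-gal counts. These too were highest in the set C library, with atilla at 44.2, 24.4 and 86.6 CPM in sets A, B and C. Without that library atilla was 5.88 and ItgaPS4 9.49. Plasmatocyte markers were higher in 6 and lower in 1 of 12, adjusted over the list alone too, with eater at 0.83 (adjusted p = 0.0024, and adjusted p = 0.36 with an estimated correlation). Integrin and adhesion genes were higher in 11 and lower in 0 of 13, adjusted over the list alone too, with mys at 1.63 (adjusted p = 2.4e-05, and adjusted p = 0.36 with an estimated correlation). ERK pathway and immediate early genes were lower in 8 and higher in 2 of 13, adjusted over the list alone too, with the feedback inhibitor genes sty at -1.83 and aos at -2.15 (adjusted p = 0.0012, and adjusted p = 0.12 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 57 of 86 (61 adjusted over the list alone), with RpL3 at 525 ± 81.6 against 1040 ± 131 CPM (adjusted p = 4.4e-08, and adjusted p = 0.65 with an estimated correlation). Proteasome genes were higher in 25 and lower in 0 of 36, adjusted over the list alone too, with Rpt4 at 0.77 (adjusted p = 9e-04, and adjusted p = 0.42 with an estimated correlation). Oxidative phosphorylation genes did not pass as a group, with 6 higher and 8 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.82). Neither did the reported Integrator targets, with 5 higher and 2 lower of 10, adjusted over the list alone too (adjusted p = 0.054, 0.048 with the replicate block, and adjusted p = 0.27 with an estimated correlation). Among these, Mkp3 was at -0.95, ana at -1.14 (-0.57, adjusted p = 0.19, with Mock as the control), pst at 0.32, Hml at 5.32, CG6847 at 1.79 and Pepck1 at 3.48 (4.12 without the set A control and 2.86 without the set C control). CG8620 was at a ratio of 84.2 (28.4 to 411), with a fitted value of 6.19 that was 6.99 without the set C control. Naam was 0.26 (adjusted p = 0.38), and Sirup was 0.49 (adjusted p = 0.11) and passed without the filter (0.54, adjusted p = 0.049) and without the set C control (0.77, adjusted p = 0.025). MtnA was 0.68 (SE 1.32, adjusted p = 0.69, 2.5e-05 with the replicate block, and at least 0.14 in its other alternatives). Heat shock proteins had 8 higher and 1 lower of 15 (9 and 2 adjusted over the list alone), at an adjusted p of 0.14, 0.022 with the replicate block and adjusted p = 0.72 with an estimated correlation.

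With Pp2A-29B dsRNA, 1825 genes were higher and 1552 lower (38.8%). TM4SF fell to 5.6 ± 3.22 from 71 ± 19.8 CPM (SD, n = 3; log2 -3.66, SE 0.34, adjusted p = 1.5e-07), and upd1, which encodes a ligand of the JAK/STAT pathway, to 2.3 ± 0.79 from 20.1 ± 1.69 CPM (-3.12, SE 0.22). 5-HT1B (-3.15), Notum (-2.97), CG6118 (-3.12) and beat-IIIa, inseparable from CG34106 (-3.28), fell as well. The highest by the naming rule were alphaTub85E (6.29, SE 0.88), Ance (5.98), Ect3 (5.74), CG43175 (5.30, SE 0.37), Dgk (5.12) and CG7778 (4.97, SE 0.29). As with mts dsRNA, the set C library lay highest, with Ect3 at 10.9, 6.52 and 28.8 CPM in sets A, B and C. Without it the log2 values were 5.36 for alphaTub85E, 4.89 for Ance, 4.93 for Ect3, 3.90 for Dgk, 3.98 for mdu (4.67 with it) and -3.90 for CG6118. Ance was 9.74 without the set B control and 5.38 without the set C control. At least 4-fold changes were seen in 506 higher and 101 lower genes, and 28.7% of the higher genes were under 1 CPM in Mock.

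Oxidative stress genes rose with Pp2A-29B dsRNA, 8 of 12 with 0 lower (9 and 0 adjusted over the list alone; camera adjusted p = 2.2e-05, and adjusted p = 0.026 with an estimated correlation), with GstD1 at 428 ± 68.4 CPM (2.38, SE 0.12) and GstD2 at least 21.8-fold higher. Further groups passed at the preset correlation alone. Mitosis genes were lower in 23 and higher in 0 of 29, adjusted over the list alone too, with asp at -1.0 and polo at -0.64 (adjusted p = 1.7e-06, and adjusted p = 0.066 with an estimated correlation). Lamellocyte markers were higher in 8 of 9, adjusted over the list alone too, with PPO3 at 3.20 and cher at 1.29 (adjusted p = 3.7e-06, and adjusted p = 0.24 with an estimated correlation), again highest in set C, where atilla was at 28.7 CPM against 9.08 and 5.54 in sets A and B (log2 4.63, and 3.65 without set C). Plasmatocyte markers were higher in 7 and lower in 1 of 12, adjusted over the list alone too, with Hml at 63.5 ± 4.8 CPM (4.46) and the phagocytic receptor gene eater at 1.04 (adjusted p = 1e-04, and adjusted p = 0.23 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 64 and higher in 0 of 86 (69 and 1 adjusted over the list alone), with RpL3 at -0.96 (adjusted p = 1.7e-11, and adjusted p = 0.57 with an estimated correlation). ERK pathway and immediate early genes were lower in 8 and higher in 2 of 13, adjusted over the list alone too, with sty at -1.42 and aos at -2.14 (adjusted p = 0.0046, and adjusted p = 0.17 with an estimated correlation). Proteasome genes were higher in 18 and lower in 0 of 36 (20 and 0 adjusted over the list alone), with Rpt4 at 0.55 (adjusted p = 0.0058, and adjusted p = 0.5 with an estimated correlation). Reported Integrator targets were higher in 6 and lower in 1 of 10, adjusted over the list alone too (adjusted p = 0.0025, and adjusted p = 0.088 with an estimated correlation). Their members split: CG6847 was at 3.43, Pepck1 at 3.33 (3.97 without the set A control and 2.72 without the set C control), CG8620 at a ratio of 68.7 (23.1 to 336; fitted value 5.93, and 6.72 without the set C control) and Sirup at 0.89, whereas Mkp3 was at -0.71 and ana at -0.34 (SE 0.28, adjusted p = 0.37). Naam (0.35, adjusted p = 0.26) and MtnA (-0.19, SE 1.34) did not pass. pst was 0.28 and missed the threshold without the set C control (0.25, adjusted p = 0.058) and without Pp2A-29B set A (0.24, 0.068). Genes of oxidative phosphorylation did not pass (1 higher and 10 lower of 68, 0 and 2 adjusted over the list alone; camera adjusted p = 0.13).

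**Figure D2:**
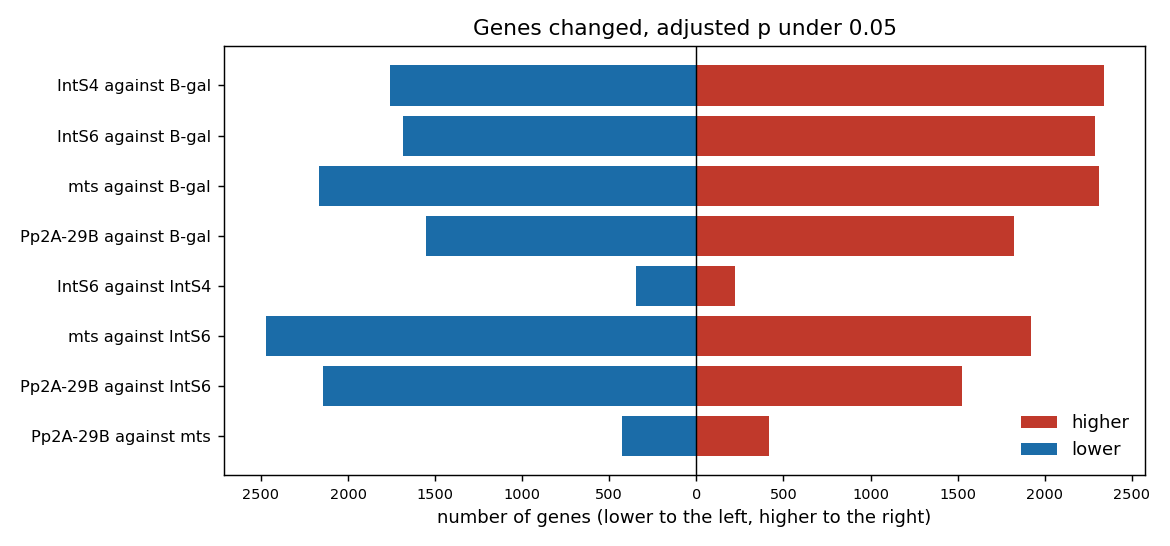
Number of genes higher and lower (bars from 0; adjusted p under 0.05, 8704 genes tested) in each dsRNA group against B-gal and in the 4 direct comparisons. Against B-gal the numbers run from 1825 to 2338 higher and from 1552 to 2165 lower, and the direct comparisons within each pair call 570 (IntS6 and IntS4) and 844 genes (Pp2A-29B and mts).

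The 4 dsRNA groups were compared for genes they share. Ance, alphaTub85E, Ect3, Dgk, mdu and CG43175 had the largest increases common to all 4 among genes with a mean log2 CPM of at least 2. LUBEL, nAChRalpha5, Notum, CG6118, the adenylyl cyclase gene Ac3 and the presynaptic gene Rim had the largest common decreases among them. CG43175 was at 6.46, 5.44, 5.67 and 5.30 with IntS4, IntS6, mts and Pp2A-29B dsRNA, and Ac3 at -1.52, -1.45, -1.65 and -1.12. In all, 907 genes were higher and 577 lower in all 4. Libraries labelled IntS4 and IntS6 dsRNA called 3315 genes the same way and 6 in opposite ways (r = 0.95 across genes), and mts and Pp2A-29B 2947 and 4 (r = 0.89). Across the pairs the numbers were 2124 and 376 for IntS4 and mts, 1900 and 225 for IntS4 and Pp2A-29B, 2133 and 354 for IntS6 and mts, and 1932 and 214 for IntS6 and Pp2A-29B, with r from 0.52 to 0.68. Genes are not independent replicates in these correlations. Independent lists of the same sizes would share 615 higher and 340 lower genes for IntS4 and IntS6 (observed 1998 and 1317), and 485 and 386 for mts and Pp2A-29B (observed 1576 and 1371). Simulated unchanged groups against 1 shared simulated B-gal group had 0 shared calls on average, with r of 0.47 to 0.49 and a covariance of 0.0744 to 0.0757. With no gene changed, hardly any call is made. That 0 therefore does not show how much a shared control adds when many genes are called. No replicate-set effect was simulated. The observed covariance exceeded the simulated one by 2.24 for IntS4 and IntS6, by 1.12 for mts and Pp2A-29B, and by 0.918 to 1.09 for the 4 cross pairs. With B-gal as the control of the first and Mock of the second, 3150 and 2704 genes were called the same way in the 2 pairs. Mock and B-gal libraries of the same set deviated together (correlations of 0.57 to 0.79). Mock is therefore no independent control, and these numbers do not exclude shared control noise.

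**Figure D3:**
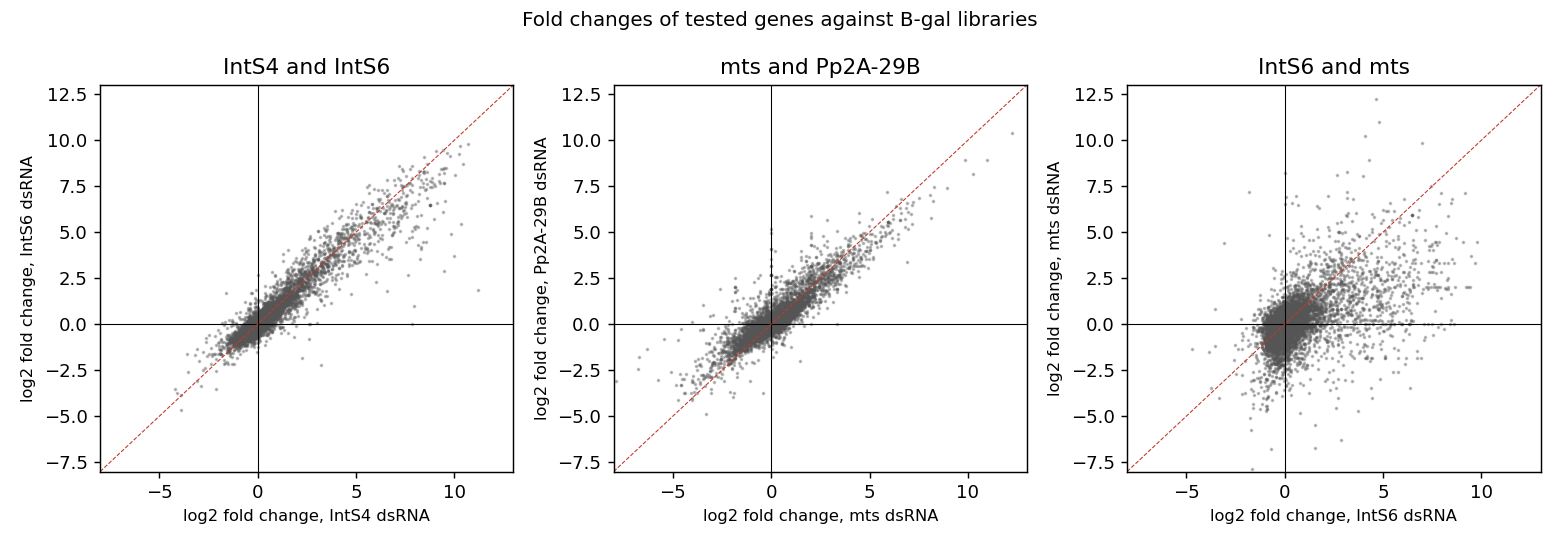
Log2 fold changes against B-gal of 8704 genes, 1 point per gene, for IntS4 and IntS6, mts and Pp2A-29B, and IntS6 and mts dsRNA, with a dashed line where both are equal. Points follow the line within the first pair (r = 0.95) and the second (r = 0.89) and scatter more between IntS6 and mts (r = 0.54), and values of genes near 0 counts in B-gal depend on the prior count.

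Genes split between the pairs in sets of their own. A set of 577 genes was higher in both Integrator-labelled groups and not called in either PP2A depletion, and 408 genes were higher in both PP2A depletions and not called in either Integrator-labelled group. A further 92 genes were higher in the first pair and lower in the second, and 46 the reverse. The nuclear receptor gene Hr38 was of the first kind, at 3.19 and 2.16 with IntS4 and IntS6 dsRNA and -2.97 and -2.10 with mts and Pp2A-29B dsRNA (-4.21 without the mts set C library). Of the 886 genes at least 4-fold higher in the libraries labelled IntS4 dsRNA, 857 (96.7%) were called higher with IntS6, 540 (60.9%) with Pp2A-29B and 465 (52.5%) with mts dsRNA. Of the 201 genes at least 4-fold lower with mts dsRNA, 152 (75.6%) were called lower with Pp2A-29B, 88 (43.8%) with IntS4 and 60 (29.9%) with IntS6 dsRNA. Being called in 1 group and not in another is no test of the difference, which the direct comparisons give.

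Directly compared, libraries labelled IntS6 and IntS4 dsRNA differed in 570 genes, 222 higher and 348 lower with IntS6. The autophagy gene Atg18b was far lower, at 8.24 ± 0.41 against 229 ± 9.46 CPM (SD, n = 3), a log2 difference of -4.79 (SE 0.20, adjusted p = 3.1e-11). alphaTub85E (-3.31), FASN2, a fatty acid synthase gene (-2.07, SE 0.32), and IntS4 (-2.95, and -1.45 without the IntS4 set A library) were the next by the naming rule, and CAP (1.62), Cln7 (1.53), tutl (1.49) and CG3770 (1.38) were the highest. Reported Integrator targets were lower in 4 and higher in 0 of 10, adjusted over the list alone too (camera adjusted p = 0.00012, and adjusted p = 0.026 with an estimated correlation), with Pepck1 at -1.79, ana at -1.40 and Sirup at -0.64. Heat shock proteins were lower in 5 of 15 (11 adjusted over the list alone), with Hsp68 at -0.68 (adjusted p = 0.00014, and adjusted p = 0.35 with an estimated correlation). Hsp68 missed the threshold without any 1 IntS4 library or without IntS6 set A or B (-0.73 to -0.58, adjusted p = 0.053 to 0.13). Sirup missed it without IntS4 set A or B or IntS6 set B or C (-0.68 to -0.52, adjusted p = 0.052 to 0.15). Small nuclear RNAs made by RNA polymerase II were lower in 5 of 16 (6 adjusted over the list alone), with snRNA:U4:38AB at 38.2 ± 7.16 against 154 ± 20 CPM (adjusted p = 6.3e-05, and adjusted p = 0.24 with an estimated correlation). Short RNAs of this kind are poorly kept by such libraries and their copies share reads, so these values are uncertain. IntS4 and IntS6 counts were each higher in their own libraries, so no direction here is tied to a measured loss of either transcript.

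Between mts dsRNA and libraries labelled IntS6 dsRNA, 1921 genes were higher and 2473 lower with mts. Tig stood at 8.24 ± 0.962 against 466 ± 115 CPM (SD, n = 3; -5.81, SE 0.19, adjusted p = 1.1e-13), and tinc (-5.70), the transcription factor gene Kah (-5.45) and SP1029 (-5.42, SE 0.15) followed. Higher with mts were the adenylyl cyclase gene Ac78C, at 54.9 ± 8.01 against 3.05 ± 0.825 CPM (4.17, SE 0.22), Gpo1 (2.41), Mcad (2.41) and CG15347 (2.38). Reported Integrator targets were lower in 7 and higher in 0 of 10 (8 and 0 adjusted over the list alone; camera adjusted p = 2e-10, and adjusted p = 0.0016 with an estimated correlation), with pst at -3.38 and ana at -5.22. ERK pathway and immediate early genes were lower in 11 and higher in 1 of 13, adjusted over the list alone too (adjusted p = 3.7e-05, and adjusted p = 0.046 with an estimated correlation), with Hr38 at -5.13 and rho at -1.85. Without the mts set C library Hr38 was -6.36 and vkg, an extracellular matrix gene, was -4.39. Oxidative phosphorylation genes were higher in 50 and lower in 3 of 68 (51 and 3 adjusted over the list alone), with ND-B16.6 at 1.14 (adjusted p = 1.8e-07, and adjusted p = 0.46 with an estimated correlation). Extracellular matrix genes were lower in 12 and higher in 0 of 15 (12 and 1 adjusted over the list alone), with vkg at -3.77 (adjusted p = 4.6e-07, and adjusted p = 0.14 with an estimated correlation). Lamellocyte markers were higher in 8 and lower in 1 of 9, adjusted over the list alone too, with atilla at 5.79 (adjusted p = 0.0038, and adjusted p = 0.47 with an estimated correlation). DNA replication genes were higher in 12 and lower in 3 of 20 (13 and 3 adjusted over the list alone), with CycE at 1.42 (adjusted p = 0.015, and adjusted p = 0.62 with an estimated correlation).

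Between Pp2A-29B dsRNA and libraries labelled IntS6 dsRNA, 1527 genes were higher and 2145 lower with Pp2A-29B. Tig (-6.05, SE 0.19), the adhesion protein gene Glt (-4.56, and -5.67 without the Pp2A-29B set C library), NtR (-4.50) and tinc (-4.50) were the lowest by the naming rule. Ac78C (3.14, 26.7 ± 7.69 against 3.05 ± 0.825 CPM, SD, n = 3), CG10232 (2.74), the ephrin receptor gene Eph (1.87) and mamo (1.87) were the highest by it. Reported Integrator targets were lower in 8 and higher in 0 of 10, adjusted over the list alone too (camera adjusted p = 1.4e-11, and adjusted p = 0.0013 with an estimated correlation), with pst at -3.42 and Sirup at -2.90. Extracellular matrix genes were lower in 13 of 15, adjusted over the list alone too, with trol at -1.78 (adjusted p = 6.6e-08, and adjusted p = 0.1 with an estimated correlation). Oxidative phosphorylation genes were higher in 33 and lower in 1 of 68, adjusted over the list alone too, with ND-MLRQ at 0.81 (adjusted p = 2e-06, and adjusted p = 0.5 with an estimated correlation). DNA replication genes were higher in 14 and lower in 3 of 20, adjusted over the list alone too, with CycE at 1.32 (adjusted p = 0.00039, and adjusted p = 0.46 with an estimated correlation). ERK pathway and immediate early genes were lower in 11 of 13, adjusted over the list alone too, with Hr38 at -4.25 (adjusted p = 0.00024, and adjusted p = 0.068 with an estimated correlation).

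The 2 PP2A depletions differed in 844 genes, 415 higher and 429 lower with Pp2A-29B than with mts dsRNA. Phosphatase genes were among those that differed. Pp4-19C, the catalytic subunit of PP4, stood at 17.7 ± 0.687 against 3.71 ± 0.771 CPM (SD, n = 3), a log2 difference of 2.25 (SE 0.15, adjusted p = 6.9e-08). The PP1 genes flw (1.01, SE 0.11) and Pp1alpha-96A (0.85, SE 0.10) and the PP6 gene PpV (0.79, SE 0.11) were higher too. Of 8 related phosphatase genes, 5 were higher and 0 lower (6 and 1 adjusted over the list alone; camera adjusted p = 1.7e-11, and adjusted p = 0.0068 with an estimated correlation). Mitosis genes were higher in 10 and lower in 0 of 29 (18 and 0 adjusted over the list alone; adjusted p = 3e-07, and adjusted p = 0.048 with an estimated correlation), with CycB at 0.49 and stg at 0.64. Lamellocyte markers were lower in 6 of 9 (7 adjusted over the list alone), with the prophenoloxidase gene PPO3 at 52.3 ± 28.6 against 142 ± 52.1 CPM (-1.44, SE 0.29) and cher at -0.78 (adjusted p = 8.9e-06, and adjusted p = 0.25 with an estimated correlation). Kah (1.73), CG6847 (1.65) and the ceramidase gene CDase (1.52) were among the highest, and Pp2A-29B itself (-1.89), Myo28B1 (-1.44) and CG3348 (-1.33) among the lowest. The number of changed genes depended on single libraries. It was 262 without Pp2A-29B set A, 331 without Pp2A-29B set B, 372 without mts set A and 469 without mts set C, and 1462 with the replicate block.

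**Figure D4:**
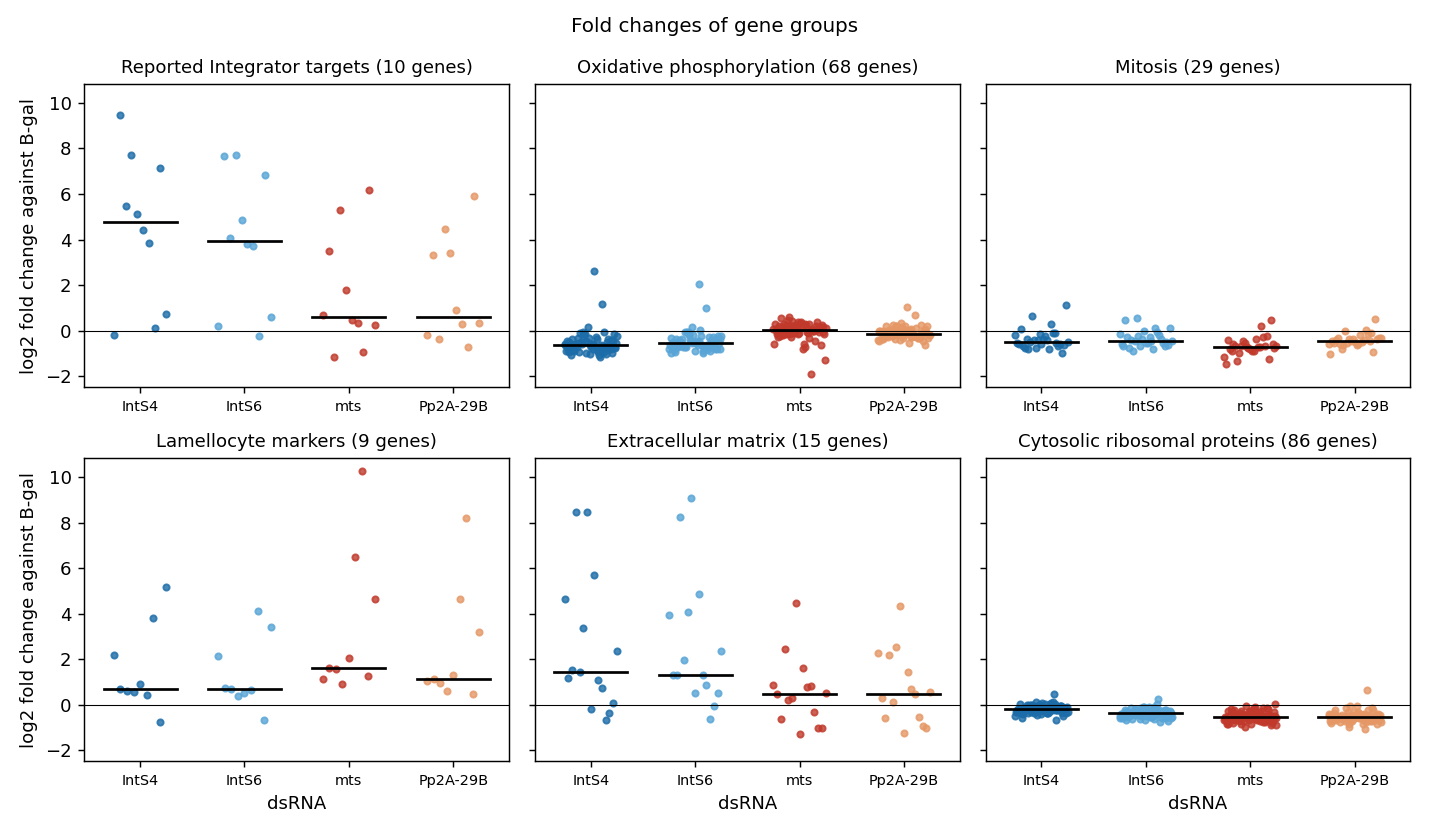
Fitted log2 fold changes against B-gal, 1 point per tested gene with lines at medians, of reported Integrator targets (10 genes), oxidative phosphorylation (68), mitosis (29), lamellocyte markers (9), extracellular matrix (15) and cytosolic ribosomal proteins (86) in the 4 dsRNA groups. The median of the Integrator targets is 4.79 and 3.94 in the libraries labelled IntS4 and IntS6 dsRNA and 0.58 and 0.62 with mts and Pp2A-29B dsRNA, and that of oxidative phosphorylation is -0.61, -0.53, 0.04 and -0.14, with values of genes near 0 counts in B-gal depending on the prior count.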

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

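Fits without ribosomal RNA entries or with a term for ribosomal RNA composition, and reaches other than 10 kb around snRNA genes, were chosen only after seeing the data. The counts of changed genes, the calls shared between dsRNA groups and the 4 targeted genes stayed within 1.5 times their value and on their side of 0 with DESeq2, RLE factors, no filter, only the 2 groups compared and both ribosomal RNA fits. No gene called in both the reported fit and 1 of these fits changed direction. Mock as the control was run only for the 4 dsRNA groups against B-gal, and for shared calls as the control of 1 group. These numbers too stayed within 1.5 times their value, and directions of single calls were not compared there. A minimum change of 1.5-fold, which by construction leaves fewer genes, gave 789, 704, 1394 and 775 lower genes with IntS4, IntS6, mts and Pp2A-29B dsRNA. With an estimated correlation the lists past the test went from 11 to 0 for B-gal and Mock, from 17 to 2 with IntS4, 18 to 2 with IntS6, 14 to 2 with mts and 14 to 1 with Pp2A-29B dsRNA. They went from 8 to 1 for IntS6 against IntS4, 9 to 2 for mts against IntS6, 12 to 1 for Pp2A-29B against IntS6 and 18 to 2 for Pp2A-29B against mts. The median over genes downstream of snRNA genes was reversed at a reach of 20 kb (0.01, against -0.16 at 10 kb), and the cause was not tested.

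The replicate block raised the number of genes that differ between Pp2A-29B and mts from 844 to 1462, and all 844 were among them. Besides the values given beside results, the block moved 2 lists of paired comparisons across the threshold, both between Pp2A-29B and mts: germline (adjusted p = 0.074, and 0.038 with the block) and glycolysis genes (0.039, 0.055). It changed no other call of a list or of a gene named here in the paired comparisons. On the third principal component the set C library lay lowest within each group, so a set effect may run through the other 4 comparisons too. Those did not pass the pairing check, which does not show them to be unpaired. Their lowest same-letter correlations were -0.03 for Pp2A-29B and B-gal (3 of 6 libraries correlated best with their own letter), 0.06 for IntS6 and IntS4 (5 of 6), -0.04 for mts and IntS6 (4 of 6) and -0.04 for Pp2A-29B and IntS6 (3 of 6). The block gave 3894, 945, 4847 and 4162 changed genes there, against 3377, 570, 4394 and 3672.

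Leaving out 1 library at a time left the log2 value of IntS4 in its own libraries between 1.52 and 3.47, of IntS6 between 0.76 and 1.78, of mts between -1.40 and -1.05 and of Pp2A-29B between -1.84 and -1.73. The number of genes that differ between Pp2A-29B and mts ran from 262 (without Pp2A-29B set A) to 1098 (without Pp2A-29B set C), with 650 under the ribosomal RNA composition term, of which 531 were among the 844. The cause of the range was not tested. That term splits libraries at a 10% share of the pre-rRNA gene CR45845, with 7 below, none of them from mts, and 11 above. Depth limits what can be said of genes near 0 counts in B-gal, since 3545828 to 6325688 counts per library lay outside ribosomal RNA. Over the 282 gene values named, 3851 of 3883 recomputed values kept their direction and side of the threshold, 14 passed it where the reported one did not, 18 lost it and 0 reversed.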

Other observations

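Of the tests given here, those of a change on both strands around snRNA genes, of gene span and of next genes were written down before their results were seen. For both strands, for next genes and for read-through past snRNA genes, the reading of the result was changed to undecided after it was seen. Those of read-through past snRNA genes, overlapping reads, related phosphatases, own-gene counts and other splits of the libraries were chosen only after the result was seen. Markers of germline and follicle cells were lower with mts dsRNA, 6 of 7 with 0 higher, adjusted over the list alone too (median -1.05; camera adjusted p = 0.00066, and adjusted p = 0.17 with an estimated correlation). With Pp2A-29B dsRNA 5 of 7 were lower and 0 higher, adjusted over the list alone too (median -0.98; adjusted p = 0.0013, and adjusted p = 0.2 with an estimated correlation). The Maf transcription factor gene tj stood at 32.8 ± 5.03 and 46.7 ± 7.27 CPM in the 2 depletions against 157 ± 12.5 with B-gal dsRNA (SD, n = 3). The piRNA pathway genes piwi (-2.06 and -1.29), AGO3 (-1.23 and -1.12) and krimp (-1.05 and -0.71) fell as well. In the libraries labelled IntS4 dsRNA 5 were lower and 0 higher, adjusted over the list alone too, at an adjusted p of 0.052, 0.02 with the replicate block and adjusted p = 0.45 with an estimated correlation. The list also passed at the preset correlation between B-gal and Mock (median 0.20, adjusted p = 0.046). Neuronal markers were lower in 3 and higher in 0 of 5 with mts dsRNA (adjusted over the list alone too) and with Pp2A-29B dsRNA (3 and 1 adjusted over the list alone), at an adjusted p of 0.024 and 0.028, and adjusted p = 0.42 with an estimated correlation for each. Among them were Syn (-3.09 and -2.55), Gad1 (-2.15 and -1.87) and the calcium channel gene cac (-1.23 and -0.89). Only 5 of the 14 neuronal genes found for the list passed the filter.

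Apoptosis genes were higher in 9 of 11 in the libraries labelled IntS4 dsRNA, adjusted over the list alone too, and in 8 of 11 with IntS6 (9 adjusted over the list alone), with 0 lower in either. Their adjusted p was 0.008 and 0.015, and adjusted p = 0.23 and 0.25 with an estimated correlation. The cell death gene hid was at 3.65 and 2.72 and the TNF ligand gene egr at 4.94 and 5.17. The cell death gene rpr had 3 B-gal counts and a ratio of 135 with IntS4 (95% counting interval 45.8 to 657) and 45.5 with IntS6 dsRNA (15.2 to 224), and its fitted values of 6.91 and 5.32 were 7.72 and 6.12 without the set B control. With mts dsRNA 8 were higher and 1 lower, adjusted over the list alone too (adjusted p = 0.042, and adjusted p = 0.39 with an estimated correlation), with Dronc at 1.11 and Dark at 0.66. Spliceosome genes were lower in 11 of 20 in both Integrator-labelled groups, with 2 higher in IntS4 and 0 in IntS6 (11 lower and 3 or 0 higher adjusted over the list alone). Among them were B52 (-1.13 and -0.89) and Prp8 (-0.59 and -0.68), at an adjusted p of 0.023 and 0.0029, and adjusted p = 0.57 and 0.46 with an estimated correlation. Small nucleolar RNAs were lower in 47 and higher in 2 of 136 with mts dsRNA (43 and 2 adjusted over the list alone; median -0.76; adjusted p = 0.0013, and adjusted p = 0.67 with an estimated correlation). Between Pp2A-29B and mts dsRNA 10 were higher and 0 lower (8 and 0 adjusted over the list alone; median 0.63; adjusted p = 1.3e-09, and adjusted p = 0.45 with an estimated correlation). Short RNAs of this kind are poorly kept by such libraries.

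Several genes just downstream of small nuclear RNA genes, on the same strand, were far higher in the libraries labelled IntS4 dsRNA than in those labelled IntS6 dsRNA: CG15482 (2L, 13210773 to 13211814, minus strand; 235 ± 18 against 2.44 ± 0.811 CPM, log2 -6.58), CG16820 (28.5 ± 2.32 against 0.344 ± 0.253) and CG13962 (18.7 ± 0.821 against 0.022 ± 0.038), chosen after their values were seen, and Atg18b, which overlaps a U4 gene. Reads of the snRNA counted on overlapping genes stay open for the 2 overlapping genes that were lower with IntS6 dsRNA, Atg18b and FASN2 (of 6), and by definition do not apply to the 4 lower genes of the 10 same-strand ones within 10 kb that overlap no snRNA gene. Transcripts that run on past snRNA ends with IntS4 dsRNA may account for the genes. The median of 16 same-strand genes within 10 kb was -0.16, at percentile 2.14 of 10000 matched random lists. The 16 include the genes named above, whose values were seen before this test was chosen, so the percentile is no independent support. The gap of -0.38 to opposite-strand genes missed the 0.5 that the test asked for, which by its rule counted against the explanation. That reading was changed to undecided after it was seen, because the 0.5 was met at 2 kb (medians -1.16 and 0.23). It was missed at 5 kb (-0.25 and 0.23), 10 kb (-0.16 and 0.22) and 20 kb (0.01 and 0.12). A change on both strands had, by the rule written beforehand, to move the opposite-strand median the same way as the same-strand one. It did not, at 0.22 against -0.16, with 0 of 7 opposite-strand genes called lower and 1 higher (CG9426, 1.34). The explanation is left open only for the spread of these genes (SD 0.49), a criterion added after the result was seen. Moreover, 3 genes that also lie on the same strand of another snRNA gene, CG13962 among them, were counted as same-strand (median 0.19 with them).

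Some genes of phosphatases related to mts were lower with mts dsRNA but not with Pp2A-29B dsRNA: Pp4-19C was at -2.36 and -0.11, Pp1alpha-96A at -0.94 and -0.09 and PpV at -0.68 and 0.11, and the direct comparison called each of them. A weaker form of the response shared by both depletions stays open for these 3 genes, picked for their values, which lay further above the line through the 2165 genes lower with mts dsRNA (slope 0.64) than 99.4, 94.8 and 95.6% of those. That mts dsRNA acts on transcripts of related phosphatases could account for it and stays open, with 3 of the 8 tested genes lower and the dsRNA and transcript sequences not used here. A difference between loss of the catalytic and of the scaffold subunit is open too and was not tested.

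IntS4 and IntS6 counts were higher in the libraries of their own dsRNA, and reads of the added dsRNA counted on the targeted gene are a candidate explanation. The coefficient of variation between the 3 libraries was 112.7% for IntS4, above 100% of 598 genes of like mean (median 7.1%), and 68.7% for IntS6, above 99.8% of 656 (median 7.3%). Loss of Integrator raising its own subunit would, by the rule set after the result was seen, raise IntS4 with IntS6 dsRNA too. IntS4 was 0.07 (SE 0.52) there, at 11.1 to 13.8 CPM against 11.9 to 12.3 CPM with B-gal dsRNA. It was 3.02 with its own dsRNA, at 26.3 to 227 CPM, and 1.52 without the set A library. These values argue against the explanation for IntS4, provided that IntS6 dsRNA removed Integrator as IntS4 dsRNA did. Counts of the 2 targeted genes cannot show that, but the 2 groups called 3315 genes the same way and 6 in opposite ways (r = 0.95). For IntS6 the same explanation stays open, at 0.68 (SE 0.29) with IntS4 dsRNA and 1.5 with its own, or 0.76 without its set A library. IntS6 was also 0.49 with mts and 0.52 with Pp2A-29B dsRNA (adjusted p = 0.17 each). Where reads lie along the genes was not analysed here, and neither depletion can be read from these counts.

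Genes higher in both Integrator-labelled groups may be long ones, although the span of genes higher with mts or Pp2A-29B dsRNA was not tested. Of the 1998 genes higher in both Integrator-labelled groups, 1250 were also higher with mts or Pp2A-29B dsRNA. Length can thus not be tied to the Integrator-labelled groups alone. The median span of 1915 protein-coding genes higher in both was 5341 bp, against 3020 bp in 2000 random lists matched on Mock expression, above 100% of them. Their exonic length was 2660 against 2202 bp, above 100% too, while the 1265 genes lower in both had a span of 3659 against 3770 bp (percentile 17.45). Whether such genes pass their transcription on to the next gene was not decided. Of same-strand genes within 5 kb downstream of genes at least 4-fold higher with IntS4 dsRNA, 127 of 371 (34.2%) were higher, and of neighbours on the other strand 202 of 635 (31.8%), at a one-sided Fisher exact p of 0.24.

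The 6 libraries of a comparison allow 10 splits into groups of 3, too few for a share under 0.05, and these mix the replicate sets freely. Every split but the real one mixes both treatments within each group, which puts a real difference into the spread within groups. Few calls in those splits are therefore no measure of the calls made without a difference. The real split called 4094, 3977, 4476 and 3377 genes with IntS4, IntS6, mts and Pp2A-29B dsRNA, 570 for IntS6 against IntS4, 4394 for mts and 3672 for Pp2A-29B against IntS6, and the highest other split 0 in each. Between Pp2A-29B and mts the numbers were 844 and 58, so 1 split of 10 reached the real number in each of these comparisons. Between B-gal and Mock the real number was 0 and the highest other 2, and with a real number of 0 the 10 splits of 10 that reach it decide nothing. Where the libraries pair by replicate set, only 3 other splits part all 3 pairs as the real one does, and the highest of them called 0 genes for B-gal and Mock, for IntS4, IntS6 and mts against B-gal, and for Pp2A-29B against mts. The other 6 part 1 pair and keep the rest together, and among these the highest numbers were 2 for B-gal and Mock and 58 for Pp2A-29B against mts, and 0 in the remaining 3.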
